A study of Rattus norvegicus with 8 samples.

How the data were processed

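Liver RNA of 8 Fischer 344 rats was measured, 4 on the CSAA and 4 on the CDAA diet; per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Groups and rat numbers came from the sample titles. Per the submitters' processing notes the authors used FastQC, TopHat2, Cufflinks, DESeq2 and edgeR with genome build rn6; program versions, the read counter, the gene annotation and the strand setting are not given in the sources used here.

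The deposited data are a table of the authors' own comparison with 1 line per gene. Per the file headers, the authors' DESeq2 columns hold a mean of normalised counts over all samples (a signal), a log2 fold change with its standard error, a Wald score and p-values. The authors' edgeR columns hold a log2 fold change, a mean log2 CPM, a p-value and a false discovery rate, per the file headers. The authors' Cufflinks columns hold a value for each diet group over an assembled locus, their log2 ratio, a test score, and p- and q-values, per the file headers. These group values are taken as FPKM, the unit that Cufflinks writes there; the header does not name it. They pool the replicates, so they are the authors' group values without SD. The deposited log2 ratios of Cufflinks equal the log2 of CDAA over CSAA within 1.20e-05 for the 2440 genes with both values above 0, and its deposited test score has the opposite sign in all 2440. The direction of the authors' DESeq2 and edgeR columns was read from the group FPKM: the DESeq2 sign was that of CDAA over CSAA for 2457 of 2462 genes, and the DESeq2 and edgeR signs were alike in all 2462. The table is selected: its highest values are an adjusted p of 0.00986 for DESeq2, a false discovery rate of 0.0100 for edgeR and a q of 0.00980 for Cufflinks, all from the authors' columns.

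This selection shapes what the values can show. Fold changes of genes picked for passing 3 tests tend to overstate small effects, no gene below an absolute DESeq2 log2 fold change of 0.599 is in the authors' table, and weakly expressed genes needed larger changes to enter. The authors' DESeq2 folds were smaller in size than the edgeR folds for 2361 genes, with a median difference of 0.04, and 58 genes differed by over 1.5 times. Between the authors' DESeq2 and Cufflinks folds, 80 genes differed by over 1.5 times. A Cufflinks locus can span several genes: 16 genes shared 5 loci, so their FPKM are not those of the single gene. Reads of near-identical copies (P450, globin, major urinary protein, metallothionein and MHC genes) can be split between them in ways the sources used here do not state, and with an unstated strand setting reads of overlapping genes cannot be told apart. The depth of each rat is not given in the sources used here; the ratio of mean normalised count to mean CPM puts the typical normalised library at about 14100000 counted reads.

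The design fixed before the data were examined was a count or limma test with 4 rats against 4, and, for a table of the authors' own values, a description of those values at an adjusted p of 0.05 without a test across rats. The latter applied. The main value is the authors' DESeq2 log2 fold change, and genes were counted by direction. The 37 gene lists were written in advance from textbook functions (876 symbols). Symbols were matched to the table directly or through current symbols and synonyms of the RefSeq gene table of assembly GRCr8, which was used for names only and recognised 2332 of the 2462 symbols; 867 list entries were left after aliases were merged and 3 symbols that matched nothing were dropped. List membership was counted as higher, lower or not listed, and no enrichment against unlisted genes was computed. A two-sided Fisher's exact test of direction within a list against all other listed genes, with Benjamini-Hochberg adjustment over the 26 lists with at least 5 listed members, was added after the data were seen; it treats genes as independent, which co-regulated genes are not.

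The rule for named genes, fixed in advance, took the 10 largest rises and 10 largest falls with at least 1 FPKM in the higher group, a finite fold in all 3 programs and a symbol that is not a LOC, RGD, AABR or ENSRNOG identifier. It added up to 4 members of each list with the largest absolute change, up to 2 more of the opposite direction, and 31 genes chosen by name; 165 genes met it, and the text gives most of them; some are not reported here. Coordinates are those of the authors' Cufflinks loci in rn6.

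Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Neighbouring loci were adjacent listed loci whose starts lie within 100 kb, 1 entry per locus, and their directions were permuted 10000 times. The tests were tested on simulated data with the 2462 genes and 40 runs each at p under 0.05. With no effect, the neighbour test called 2.5%, the chromosome test 7.5% and the list test on 15 genes 2.5% of runs. In these runs directions were permuted independently over genes, as the tests assume, so they do not give error rates for co-regulated genes. With 40% of neighbour pairs set alike, 50% of the genes of 1 chromosome set higher, or 97% of list members set higher, they called 100%, 85.0% and 100% of runs.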

Results

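RNA was sequenced from the livers of 8 Fischer 344 rats, an inbred strain, at 1 year of age. Per the labels, 4 rats received the choline-sufficient amino acid-defined diet (CSAA), the healthy diet of the series, and 4 received its choline-deficient counterpart (CDAA), under which hepatocellular carcinoma had developed. Choline is needed to make phosphatidylcholine and, after oxidation to betaine, gives methyl groups to the methionine cycle. The design addressed which transcripts differ between the livers of carcinoma-bearing rats and those of rats on the sufficient diet. The labels do not say whether tumour nodules were dissected or what sex the rats were. The values used here are the authors' comparison of the diet groups, so each fold change carries the standard error (SE) of the authors' model and no spread between individual rats was computed. Over the genes of the authors' deposited table, the mean normalised count and the mean CPM (counts scaled to the library size) corresponded to about 14100000 counted reads in a typical normalised library.

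Among the genes that changed, members of the joint list for the urea cycle and amino acid breakdown and of the lists for fatty acid and cholesterol synthesis were lower in the CDAA livers, and members of the lists for the cell cycle, the extracellular matrix and the bile duct were higher. The authors' deposited table held 2462 genes, of which 1407 (57.1%) rose and 1055 (42.9%) fell in CDAA. Among the risers in the authors' deposited table the median log2 fold change was 1.65, and among the fallers it was -1.08. The genes that rose were mostly weakly expressed in the sufficient-diet group, with a median of 1.02 FPKM (fragments scaled to transcript length and library size) in CSAA and 3.91 FPKM in CDAA in the authors' deposited table. Those that fell were abundant liver transcripts, with medians of 42.4 FPKM in CSAA and 18.0 FPKM in CDAA in the authors' deposited table. A change of at least 2-fold was recorded in the authors' deposited table for 1848 genes, of which 1236 rose and 612 fell, and a change of at least 8-fold for 172 risers and 36 fallers. All 2462 genes had passed an adjusted p, false discovery rate or q of 0.01 in each of the 3 programs whose columns the authors' deposited table holds. When the count was restricted to genes of at least 5 FPKM in either group of the authors' deposited table, fallers outnumbered risers, 957 to 571. A gene outside the table either did not pass all 3 tests or was not tested, so its absence does not show that it was unchanged.

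**Figure D1:**
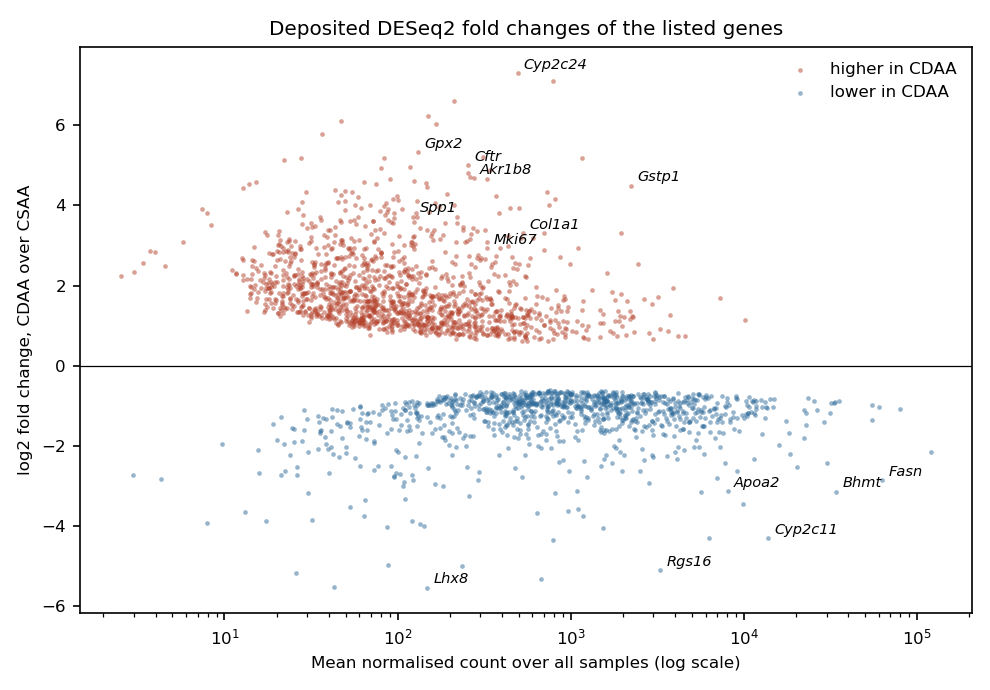
Log2 fold change of CDAA over CSAA (vertical axis) against the mean normalised count over all samples (horizontal axis, log scale) for each of the 2462 genes in the authors' deposited table. Red points are the 1407 genes that rose and blue points the 1055 that fell. No gene lies within 0.599 of 0, and the fallers sit further to the right, at higher counts, with median counts of 852 against 94.4 for the risers.

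The steepest rises in the authors' deposited table, among genes with at least 1 FPKM in the higher group, a finite fold and a symbol other than a LOC, RGD, AABR or ENSRNOG identifier, were led by Cyp2c24, a cytochrome P450 gene, at a log2 fold change of 7.31 ± 0.43 (SE), or 159-fold. Cyp2c24 (ENSRNOG00000013241) lay on chromosome 1, from 258074859 to 258139176 in build rn6, and went from 0.113 to 34.1 FPKM in the authors' deposited table. It was followed in the authors' deposited table by the unnamed transcript AC130970.1 (6.59 ± 0.38), the matrix metalloproteinase gene Mmp27 (6.03 ± 0.46) and Gpx2, a glutathione peroxidase (5.33 ± 0.36). The epithelial genes Dcdc2 (5.21 ± 0.36), Cftr, a chloride channel of bile duct cells (5.003 ± 0.39), and Ehf, an epithelial transcription factor (4.95 ± 0.43), were also among the 10 in the authors' deposited table. Gipc2 (5.18 ± 0.41), Csmd1 (5.18 ± 0.30) and Cryab, a small heat shock protein (4.89 ± 0.35), completed them in the authors' deposited table. The authors' other programs gave steeper rises by over 1.5 times for Cyp2c24 and Mmp27 in the authors' deposited table, with edgeR log2 fold changes of 8.11 and 6.81. Cufflinks exceeded DESeq2 by over 1.5 times for AC130970.1 (7.41), Gipc2 (5.90) and Ehf (5.62) in the authors' deposited table.

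The steepest fall by the same rule was that of Lhx8, a LIM homeobox gene, at -5.54 ± 0.33 (SE) in the authors' deposited table. Lhx8 (ENSRNOG00000028348; chromosome 2, 260574189 to 260596777, rn6) went from 10.7 FPKM in CSAA to 0.191 FPKM in CDAA in the authors' deposited table. Rgs16, a regulator of G protein signalling (ENSRNOG00000027024; chromosome 13, 71179909 to 71185216), fell from 170 to 3.99 FPKM, a log2 fold change of -5.09 ± 0.35 in the authors' deposited table. The male-predominant P450 gene Cyp2c11 (-4.31 ± 0.45) fell from 1087 to 39.4 FPKM and its paralog Cyp2c7 (-4.30 ± 0.57) from 506 to 13.2 FPKM in the authors' deposited table. Pclo (-3.95 ± 0.32) and Trim36 (-3.87 ± 0.65) were further fallers in the authors' deposited table, and for Trim36 and Cyp2c7 edgeR gave steeper falls, of -5.44 and -5.29. The other 4 of the 10 were Rn50_5_0815.7 (-5.19 ± 0.61), Rn50_5_0814.3 (-4.97 ± 0.58), Rn50_5_0814.6 (-4.35 ± 0.65) and Rn50_5_0815.8 (-3.88 ± 0.61) in the authors' deposited table. They lie at or beside the major urinary protein gene cluster, near-identical copies between which reads can be split, and their values differed between programs by over 1.5 times, so the values of single copies are uncertain. Rn50_5_0815.7 was at -7.27, Rn50_5_0814.3 at -6.26, Rn50_5_0814.6 at -6.05 and Rn50_5_0815.8 at -5.10 with edgeR in the authors' deposited table.

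The members of 37 gene lists, fixed before the data were examined, were counted by direction. Between them, 325 distinct members were in the authors' deposited table. A direction test, chosen after the data were seen, compared the split of each list having at least 5 listed members with that of the other listed genes (two-sided Fisher's exact test, adjusted over 26 lists). It asks whether a list leaned to a direction among genes that had already changed, not whether the list changed more often than other genes. More listed genes rose than fell, so 6 of 6 members higher gives an unadjusted p of 0.0408 and 6 of 6 lower 0.00614 (Fisher's exact test). By this test 17 of the 26 lists differed, 8 towards higher and 9 towards lower expression in CDAA.

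**Figure D2:**
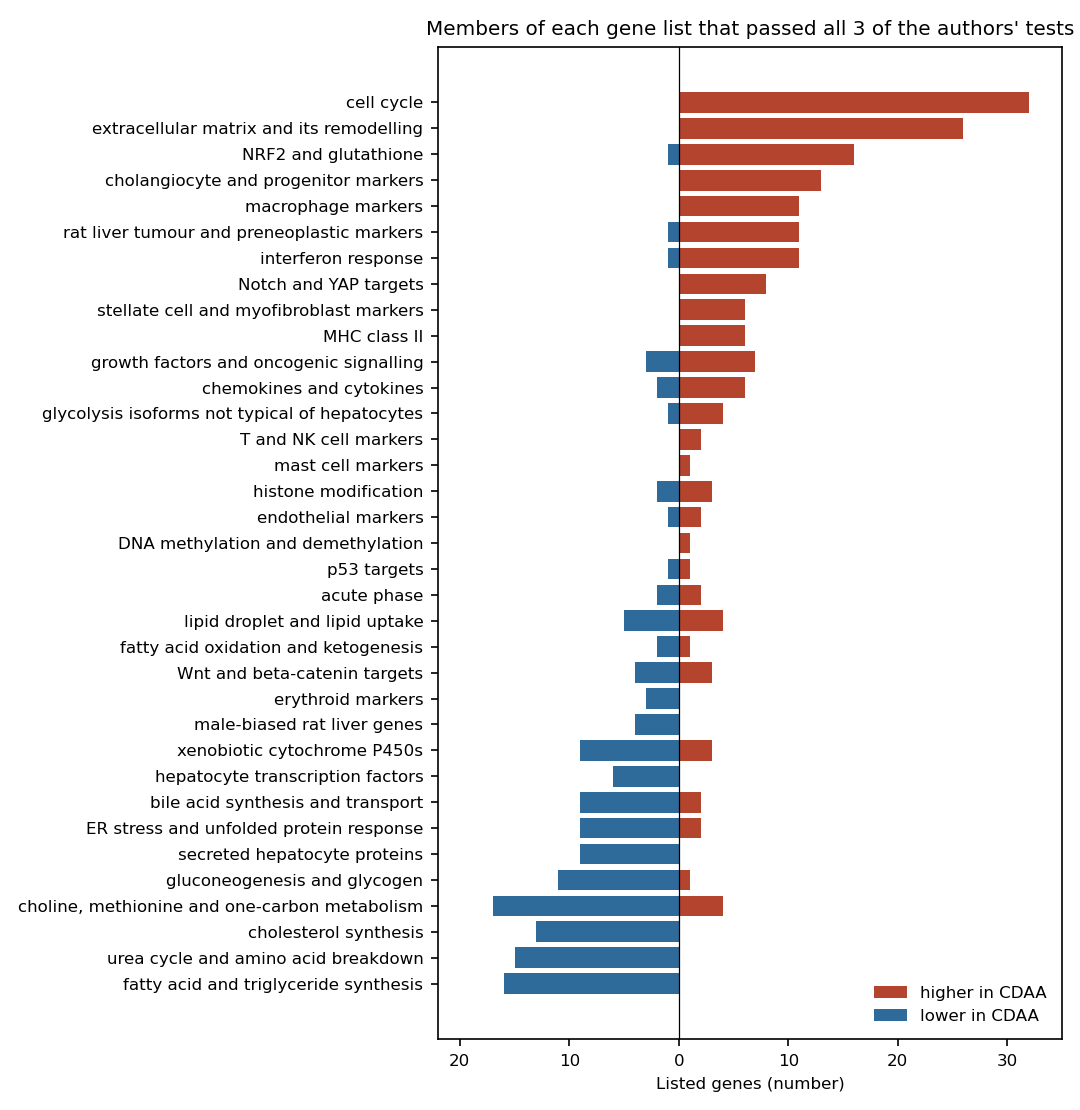
Number of members of each gene list (horizontal axis, genes) that the authors' deposited table holds as higher (red, to the right of 0) or lower (blue, to the left) in CDAA. The cell cycle list has 32 members to the right and none to the left, and the fatty acid and triglyceride synthesis list has 16 to the left and none to the right; lists with no member in the table are not drawn.

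Of 22 secreted hepatocyte proteins, 9 were in the authors' deposited table and all 9 fell (adjusted p = 0.00195, Fisher's exact test). Apoa2, an apolipoprotein of high-density lipoprotein, fell by 3.13 ± 0.39 (SE) on the log2 scale and the antithrombin gene Serpinc1 by 1.80 ± 0.11 in the authors' deposited table. Ttr, the transthyretin gene, fell from 13443 to 6364 FPKM, a log2 fold change of -1.08 ± 0.13, in the authors' deposited table. All 6 of the 14 hepatocyte transcription factors found there fell too (adjusted p = 0.0133, Fisher's exact test), among them Nr1h4, the bile acid receptor FXR (-1.48 ± 0.14), Prox1 (-1.12 ± 0.19) and Hnf4a (-0.76 ± 0.19) in the authors' deposited table. With at least a 2-fold change asked for, 4 secreted protein and 3 transcription factor genes stayed, too few for the direction test.

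In bile acid synthesis and transport, 9 of the 11 listed genes fell and 2 rose (adjusted p = 0.0215, Fisher's exact test; 19 genes in the list). The bile acid-CoA ligase Slc27a5 (-2.62 ± 0.28, SE) and the sterol 12-alpha-hydroxylase Cyp8b1 (-1.57 ± 0.35) fell, and the basolateral exporter Abcc3 rose by 4.17 ± 0.33 in the authors' deposited table, with Cyp7b1 (1.05 ± 0.22) the other riser. Of 25 xenobiotic P450 genes, 9 fell and 3 rose in the authors' deposited table, a split that passed only among genes changed at least 2-fold (adjusted p = 0.0531 over all, 0.0190 at 2-fold, Fisher's exact test). The risers were Cyp1b1 (3.37 ± 0.54), which edgeR put at 3.98, Cyp2b1 (2.33 ± 0.40) and Cyp2b2 (1.75 ± 0.35), and Cyp3a9 fell (-2.49 ± 0.55) in the authors' deposited table. All 4 listed genes of the 11 in the list named male-biased rat liver genes fell in the authors' deposited table. Beside Cyp2c11 these were the urinary protein gene Mup5 (-3.59 ± 0.61), the steroid 5-alpha-reductase Srd5a1 (-2.26 ± 0.42) and the transporter Slco1a1 (-1.33 ± 0.22) in the authors' deposited table. The list name does not describe Srd5a1, which is higher in female than in male rat liver. The Cufflinks value of Mup5 in the authors' deposited table, -4.30, covers a locus of 7 listed genes, and its mean count and mean CPM are out of proportion.

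All 15 listed genes of 23 for the urea cycle and amino acid breakdown fell in the authors' deposited table (adjusted p = 1.85e-05, Fisher's exact test), led by the proline dehydrogenase Prodh1 (-2.38 ± 0.36, SE) and including the urea cycle gene Ass1 (-1.32 ± 0.25). In gluconeogenesis and glycogen handling 11 of 12 listed genes fell (adjusted p = 0.00206, Fisher's exact test; 15 in the list), such as the glucose-6-phosphatase gene G6pc (-2.81 ± 0.30), whose Cufflinks locus also covers other listed genes, and liver pyruvate kinase, Pklr (-2.03 ± 0.22), in the authors' deposited table. The exception was Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (1.26 ± 0.37), in the authors' deposited table. The list named glycolysis isoforms not typical of hepatocytes counted 5 listed genes of 19, of which 4 rose and 1 fell in the authors' deposited table (adjusted p = 0.495, Fisher's exact test). Pfkp (2.17 ± 0.34), Hk2 (1.34 ± 0.42) and Hk1 (1.27 ± 0.32) rose and Ldha fell (-1.36 ± 0.35) in the authors' deposited table. The list name does not describe Ldha, which was at 123 FPKM in CSAA, against 0.582 for Pfkp, 0.450 for Hk2 and 1.55 for Hk1.

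Fatty acid and triglyceride synthesis had 16 listed genes of 21, all lower in the authors' deposited table (adjusted p = 1.05e-05, Fisher's exact test). Fasn, the fatty acid synthase (ENSRNOG00000045636; chromosome 10, 109987734 to 110005901, rn6), fell from 777 to 86.5 FPKM, or -2.85 ± 0.44 (SE), in the authors' deposited table. The ATP citrate lyase Acly (-2.52 ± 0.40) and the acetyl-CoA carboxylase Acaca (-2.33 ± 0.35) fell with it in the authors' deposited table. Pnpla3, a lipase-like gene, was at -3.45 ± 0.72 with DESeq2 but at -6.26 with edgeR and -6.24 with Cufflinks (387 to 5.10 FPKM) in the authors' deposited table. All 13 listed cholesterol synthesis genes of 24 were lower in the authors' deposited table (adjusted p = 8.19e-05, Fisher's exact test), such as Tm7sf2 (-1.73 ± 0.25) and Insig1 (-1.60 ± 0.48); 8 of the 13 stayed with at least a 2-fold change asked for. Fatty acid oxidation and ketogenesis had 3 listed genes of 26, with Acsl1 (-1.19 ± 0.21) and Hadh (-0.90 ± 0.27) lower and the hormone gene Fgf21 (1.18 ± 0.34) higher in the authors' deposited table. Lipid droplet and uptake genes went both ways, 4 up and 5 down of 21 in the authors' deposited table (adjusted p = 0.552, Fisher's exact test). Fabp4 (3.97 ± 0.33), Vldlr (3.31 ± 0.30) and the lipoprotein lipase Lpl (3.18 ± 0.31) rose, and the liver fatty acid-binding protein Fabp1 (-1.41 ± 0.20) and G0s2 (-1.85 ± 0.42) fell, in the authors' deposited table.

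Genes of choline, methionine and folate metabolism, the pathways that the diet acts on, were listed for 21 of 37, with 17 lower and 4 higher in the authors' deposited table (adjusted p = 0.00195, Fisher's exact test). Bhmt, which remethylates homocysteine with betaine (ENSRNOG00000011200; chromosome 2, 23236574 to 23256158, rn6), fell from 2288 to 243 FPKM, or -3.14 ± 0.24 (SE), in the authors' deposited table. Gnmt, the glycine N-methyltransferase (-2.54 ± 0.33), Nnmt (-1.42 ± 0.24) and Pemt, which methylates phosphatidylethanolamine to phosphatidylcholine (-0.77 ± 0.19), fell as well in the authors' deposited table. The S-adenosylmethionine synthase genes moved apart, the liver form Mat1a to -0.94 ± 0.22 and the non-hepatic form Mat2a to 1.24 ± 0.13, in the authors' deposited table. The other risers were the mitochondrial folate genes Mthfd1l (2.67 ± 0.33) and Mthfd2 (2.43 ± 0.32) and the ornithine decarboxylase Odc1 (0.81 ± 0.13) in the authors' deposited table. With at least a 2-fold change asked for, 10 of the 17 fallers stayed.

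Of 22 genes of DNA methylation and demethylation, 1 was in the authors' deposited table: Uhrf1, which brings the maintenance methyltransferase to replicating DNA, rose by 2.43 ± 0.37 (SE). Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2 and Tet3 were not in the authors' deposited table. Of 49 genes for histone modification 5 were listed, with the methyltransferase Setd7 (2.27 ± 0.25), Whsc1 (1.08 ± 0.17) and the demethylase Kdm6b (0.95 ± 0.22) higher and the deacylases Sirt3 (-0.73 ± 0.16) and Sirt5 (-0.69 ± 0.13) lower in the authors' deposited table (adjusted p = 1, Fisher's exact test). Ezh2 was not in the authors' deposited table.

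Of 26 rat liver tumour and preneoplastic markers, 11 rose and 1 fell in the authors' deposited table (adjusted p = 0.0261, Fisher's exact test). Gstp1, the placental glutathione S-transferase used to mark preneoplastic foci in rat liver (ENSRNOG00000018237; chromosome 1, 219291678 to 219294147, rn6), went from 16.9 to 472 FPKM, or 4.50 ± 0.35 (SE), in the authors' deposited table. The aldo-keto reductase Akr1b8 (4.68 ± 0.35), Ggt1 (4.26 ± 0.50; 4.91 with edgeR) and Gpc3, a glypican of liver tumours (3.09 ± 0.45), rose, and Igf2bp3 fell (-1.48 ± 0.27), in the authors' deposited table. Several members, such as Prom1 and Spp1, also mark bile duct cells. With members of other lists left out, 4 rose and the split did not pass (adjusted p = 0.487, Fisher's exact test). It did not pass at 2-fold either, where all 11 risers stayed (adjusted p = 0.171, Fisher's exact test). Afp and Igf2 were not in the authors' deposited table. Of 27 genes of the NRF2 pathway and glutathione metabolism, 16 rose and 1 fell in the authors' deposited table (adjusted p = 0.00517, Fisher's exact test). The cystine transporter Slc7a11 (4.56 ± 0.50; 5.26 with edgeR) and Akr7a3 (3.32 ± 0.29) rose and the transaldolase Taldo1 fell (-0.64 ± 0.12) in the authors' deposited table.

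All 32 cell cycle genes found in the authors' deposited table, of 45 in the list, rose (adjusted p = 4.06e-07, Fisher's exact test). Mki67, which encodes the Ki-67 antigen, went from 0.437 to 3.70 FPKM, or 2.94 ± 0.29 (SE), in the authors' deposited table, beside Pbk (3.09 ± 0.33), Kif20a (2.85 ± 0.32) and the cyclin gene Ccne1 (2.81 ± 0.44). Of 20 genes in the list named p53 targets, Cdkn2b rose (1.79 ± 0.37) and Sesn2 fell (-0.78 ± 0.16) in the authors' deposited table. The list name does not describe Cdkn2b, a cell cycle inhibitor gene that is not a p53 target. In the list for endoplasmic reticulum stress 9 of 11 listed genes fell (adjusted p = 0.0215, Fisher's exact test; 22 in the list), among them the chaperone gene Hyou1 (-1.23 ± 0.16) and Creld2 (-1.16 ± 0.22), and the stress transcription factor Atf3 (2.83 ± 0.38) and Trib3 (1.80 ± 0.32) rose, in the authors' deposited table. At 2-fold the split of this list no longer passed (adjusted p = 0.0774, Fisher's exact test). Growth factor and oncogenic signalling genes rose in 7 and fell in 3 of 10 listed cases in the authors' deposited table (adjusted p = 0.552, Fisher's exact test; 36 in the list), with Myc (2.74 ± 0.31), Bmp7 (2.62 ± 0.31), Pdgfb (2.15 ± 0.42) and Fgfr1 (1.40 ± 0.32) higher and Egfr (-1.39 ± 0.24) and Ghr (-0.99 ± 0.23) lower. Wnt and beta-catenin targets went both ways, 3 up and 4 down of 15, in the authors' deposited table (adjusted p = 0.541, Fisher's exact test). Rhbg (3.82 ± 0.33), whose mean count and mean CPM are out of proportion, and Nkd1 (1.47 ± 0.40) rose, and Oat (-2.37 ± 0.27) and Notum (-2.06 ± 0.34) fell, in the authors' deposited table. Of 16 Notch and YAP targets 8 were listed and all 8 rose in the authors' deposited table (adjusted p = 0.0215, Fisher's exact test), including Ankrd1 (2.25 ± 0.43), the Notch ligand Jag1 (1.86 ± 0.21), Heyl (1.67 ± 0.35) and Nrarp (1.39 ± 0.38). At 2-fold this split did not pass either (adjusted p = 0.0897, Fisher's exact test).

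**Figure D3:**
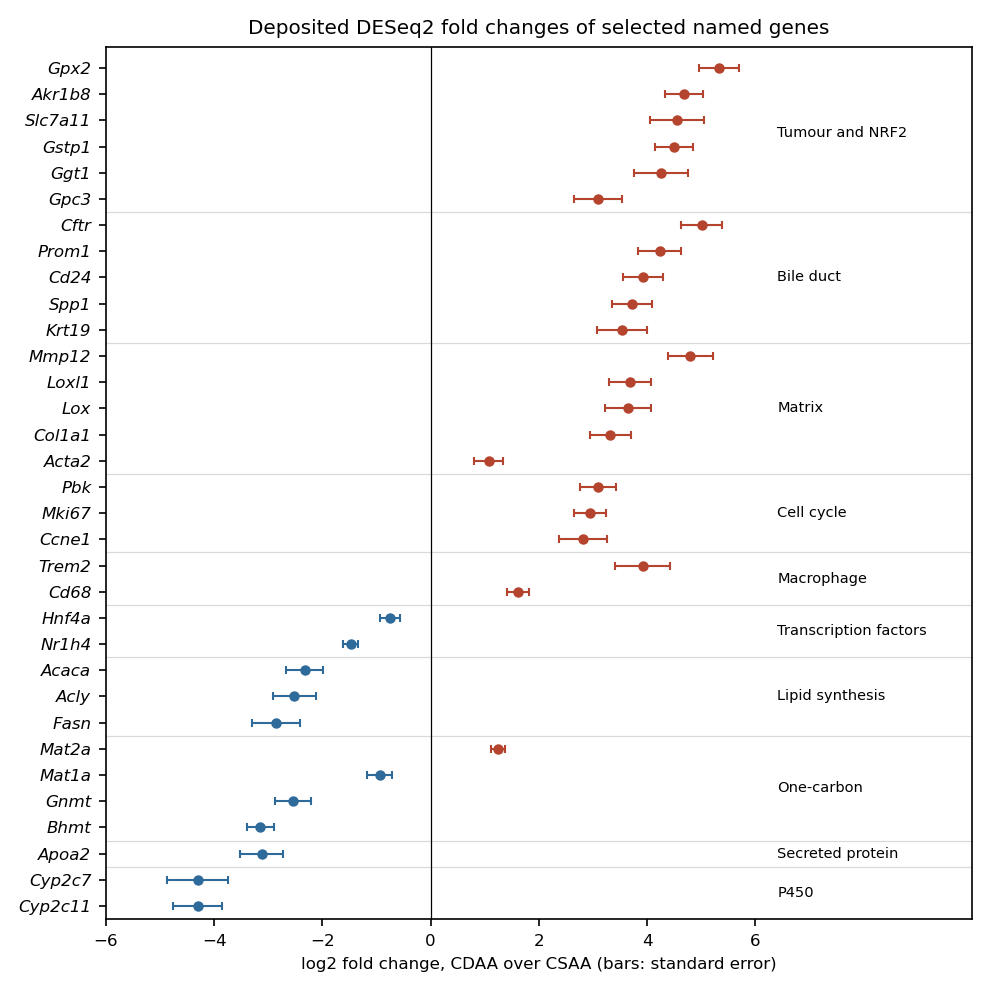
Log2 fold change of CDAA over CSAA (horizontal axis) from DESeq2 in the authors' deposited table for selected genes, grouped by function as named at the right; bars are the SE of the authors' model. The rises run from 1.07 (Acta2) to 5.33 (Gpx2) and the falls from -0.76 (Hnf4a) to -4.31 (Cyp2c11).

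Genes of the extracellular matrix and its remodelling were listed for 26 of 51, and all 26 rose in the authors' deposited table (adjusted p = 7.54e-06, Fisher's exact test). The macrophage elastase Mmp12 (4.80 ± 0.42, SE), the crosslinking enzymes Loxl1 (3.68 ± 0.39) and Lox (3.64 ± 0.42), Fbln1 (3.59 ± 0.41) and the collagen gene Col1a1 (3.32 ± 0.37) were among them in the authors' deposited table. Markers of other liver cell types moved with these groups. All 13 listed cholangiocyte and progenitor markers of 21 rose (adjusted p = 0.0028, Fisher's exact test), such as Prom1 (4.23 ± 0.40), Bicc1 (3.93 ± 0.30), Cd24 (3.92 ± 0.37), Spp1 (3.72 ± 0.37) and Krt19 (3.53 ± 0.46), in the authors' deposited table. With members of other lists left out 8 stayed. The 6 listed markers of stellate cells and myofibroblasts, of 22, rose in the authors' deposited table (adjusted p = 0.0531, Fisher's exact test), with Cygb at 2.68 ± 0.30, Vim at 1.97 ± 0.22, Des at 1.68 ± 0.34 and Acta2 at 1.07 ± 0.26. All 11 listed macrophage markers of 29 rose (adjusted p = 0.00818, Fisher's exact test), including Trem2 (3.92 ± 0.51; 4.57 with edgeR), Gpnmb (2.94 ± 0.28), Lyz2 (2.68 ± 0.32) and Cd68 (1.61 ± 0.20) in the authors' deposited table.

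Other cell types were represented by few genes. Of 23 T and NK cell markers, Icos (2.20 ± 0.36, SE) and Cd8a (1.35 ± 0.41) rose in the authors' deposited table, and Cd3e was not in it. The mast cell list of 10 had 1 member there, Hdc (2.05 ± 0.50), and the 15 B and plasma cell and 13 neutrophil markers had none in the authors' deposited table. Endothelial markers split, with Cd34 (2.51 ± 0.43) and Vwf (1.15 ± 0.27) higher and Kdr (-0.96 ± 0.11) lower of 21 in the authors' deposited table. The 3 listed erythroid genes of 10, the globin genes Hbb (-1.30 ± 0.39), Hba-a2 (-1.04 ± 0.23) and Hba-a1 (-0.97 ± 0.23), fell in the authors' deposited table.

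Among immune signals, 6 of 8 listed chemokine and cytokine genes rose (adjusted p = 0.541, Fisher's exact test; 36 in the list), such as Cx3cl1 (3.86 ± 0.38, SE), Ccl21 (3.29 ± 0.24) and Cxcl16 (2.73 ± 0.25), and Cxcl12 (-1.72 ± 0.25) and Il33 (-1.53 ± 0.31) fell, in the authors' deposited table. Ccl20 was listed at 0 FPKM in CSAA and 0.797 FPKM in CDAA in the authors' deposited table, so Cufflinks gave no ratio. DESeq2 put it at 2.84 ± 0.73 and edgeR at 6.01, at a mean count of 3.95, so the size of its rise is uncertain. The interferon response list had 11 of 12 listed genes higher in the authors' deposited table (adjusted p = 0.0261, Fisher's exact test; 32 in the list), with Oas2 at 2.39 ± 0.32, Cmpk2 at 1.91 ± 0.24 and Mx1 at 1.86 ± 0.25, and the sensor gene Ddx58 lower at -0.81 ± 0.17. Among genes changed at least 2-fold the interferon split did not pass (adjusted p = 0.0897, Fisher's exact test). All 6 listed genes of MHC class II, of 11, rose in the authors' deposited table (adjusted p = 0.0531, Fisher's exact test), among them RT1-Ba (1.87 ± 0.23) and RT1-Da (1.46 ± 0.31), members of a family with near-identical copies. Acute phase genes numbered 4 of 18, with the metallothionein Mt2A (4.34 ± 0.58; 5.41 with edgeR) and Lbp (1.71 ± 0.25) higher and Crp (-2.42 ± 0.15) and Cfb (-1.05 ± 0.18) lower in the authors' deposited table. Of the 31 genes chosen in advance to be reported in any case, 18 were in the authors' deposited table, and the 13 that were not included Alb, Cyp7a1 and Cpt1a besides those named above.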

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

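The adjusted p of 0.01, the 2-fold and 5 FPKM limits on the gene counts, and the lists without shared members or with named symbols alone were planned. The lists at 2-fold, the settings that use another program's fold, an adjusted p of 0.001 in all 3 programs, 1 FPKM in the higher group or no shared loci, and the direction test itself, were chosen after the data were seen. No paired analysis was possible because the authors' table holds no value of an individual rat. For the same reason another test or normalization, a model without a filter, another pseudocount, leaving out each rat in turn, camera with an estimated correlation and fry were not run. An adjusted p of 0.01 changed no count, by construction, since every gene in the authors' table had already passed it. A log2 fold change of at least 1 left 612 fallers against 1055, and p under 0.001 in all 3 programs left 665, by construction. At least 5 FPKM in either group left 571 risers against 1407 and 984 genes changed at least 2-fold against 1848, and moved the share of risers from 57.1% to 37.4%, since the risers were less abundant. The other settings kept these counts within 1.5 times. The direction test differed for 17 lists, for 16 without shared members, 17 with named symbols alone, 12 at 2-fold and 17 without shared loci. At 2-fold 6 lists no longer passed: secreted hepatocyte proteins, hepatocyte transcription factors, tumour markers, endoplasmic reticulum stress, interferon response, and Notch and YAP targets. The lists of secreted proteins and transcription factors kept 4 and 3 members, too few for the test. All 11 tumour marker and all 8 Notch and YAP risers stayed, but 1236 of the 1848 genes compared rose, so lists of risers stood out less. The xenobiotic P450s passed at 2-fold. Without shared members the tumour markers did not pass. Of 111 list counts under an alternative, 102 lay within 1.5 times of the main count, 9 moved further and 0 turned around. Those that moved were, at 2-fold, secreted hepatocyte proteins (9 to 4), hepatocyte transcription factors (6 to 3), fatty acid oxidation (2 to 1), cholesterol synthesis (13 to 8), choline and methionine metabolism (17 to 10) and endoplasmic reticulum stress (9 to 5), and, without shared members, male-biased genes (4 to 2), tumour markers (11 to 4) and cholangiocyte markers (13 to 8). All 329 values of the 165 named genes under edgeR or Cufflinks had the direction of DESeq2. A gene outside the authors' table has no value here under any setting.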

Other observations

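Gene families were formed from shared symbol stems after the data were seen, and 48 with at least 5 listed genes were tested for direction against the other listed genes; identifier symbols such as LOC were not counted. The hydroxysteroid dehydrogenases with the stem Hsd fell, 9 of 9 in the authors' deposited table (adjusted p = 0.0121, Fisher's exact test), among them Hsd11b1, which activates glucocorticoids (-1.66 ± 0.23, SE), Hsd17b6 (-1.63 ± 0.33) and the lipid droplet gene Hsd17b13 (-0.90 ± 0.24). Of the cytochrome P450 genes with the stem Cyp in the authors' deposited table, 20 fell and 6 rose (adjusted p = 0.0121, Fisher's exact test); Cyp3a62 rose by 2.22 ± 0.31 beside Cyp2c24. By its descriptions the authors' deposited table also holds the P450 genes LOC100361492, which rose (7.11 ± 0.44), and LOC100361547, which fell (-4.003 ± 0.43), outside this count. Of 20 genes with CD antigen symbols, 18 rose in the authors' deposited table (adjusted p = 0.0385, Fisher's exact test), led by the immune checkpoint gene Cd276 (4.24 ± 0.27) and the hyaluronan receptor Cd44 (3.94 ± 0.36), and Cd81 (-1.15 ± 0.15) and Cd302 (-0.96 ± 0.29) fell. These 3 families passed and the other 45 did not.

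All 6 Toll-like receptor genes in the authors' deposited table rose, from Tlr4 (1.01 ± 0.22, SE) to Tlr13 (1.79 ± 0.26), without passing (adjusted p = 0.196, Fisher's exact test). The unadjusted p of 0.0408 (Fisher's exact test) is the smallest that 6 genes can give towards higher expression. The flavin monooxygenase gene Fmo1 fell (-2.24 ± 0.38) and Fmo2 rose (1.54 ± 0.36) in the authors' deposited table. Ighm, an immunoglobulin heavy chain gene, fell from 237 to 15.3 FPKM (-2.94 ± 0.64) in the authors' deposited table, while the 15 B and plasma cell markers fixed in advance were not in it.

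The tests of cell composition and of sex-dependent genes below were chosen after the values were seen; those of neighbouring genes were set before their results, except the permutation within chromosomes and the values of the chromosome 13 fallers. Hepatocyte genes fell while markers of other liver cell types rose. A lower share of hepatocytes alone would lower their transcripts by a common factor, but the 9 listed secreted hepatocyte proteins ranged from -3.13 to -0.89, with a Cochran Q of 66.3 on 8 degrees of freedom. With the 15 listed genes of the urea cycle and amino acid breakdown added, not all of which are confined to hepatocytes, Q was 120.5 on 23 degrees of freedom over 24 genes. An equal rise of every other type would raise markers confined to those types alike. The 36 listed markers had a Q of 1091 on 35 degrees of freedom, ranging from -0.96 (Kdr) to 5.003 (Cftr). Some of them, such as Krt8 and Krt18, are also made by hepatocytes, so unequal rises of the markers cannot exclude an equal rise of the types. A changed composition in part, alike or different between the other cell types, and altered expression within cells remain open. Diet and carcinoma cannot be separated by the design.

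The 4 listed genes of 11 in the male-biased list fell, though Srd5a1 among them is higher in female rat liver. A larger share of females in the CDAA group would raise genes higher in female liver. The 3 listed genes of a set written for this test, Cyp2a1, Cyp3a9 and Cyp2c7, had a median log2 fold change of -2.49. All 3 are cytochrome P450 genes, and of the genes with the stem Cyp 20 fell and 6 rose. A fall of this family could hide a difference in sex. Srd5a1, a female-higher gene outside this family, also fell (-2.26 ± 0.42, SE), but a single gene cannot decide this, so the question stays open. Reads shared within the Mup gene cluster cannot account for the falls of the male-higher genes outside the cluster, Cyp2c11 and Slco1a1, and stay open for Mup5 itself. No biological explanation of this fall was tested.

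Neighbouring listed genes moved in the same direction more often than chance: 307 of 504 adjacent pairs, or 60.9%, against a permuted mean of 51.1% (permutation p = 0.0001, the smallest that 10000 permutations can give). Tandem copies with a shared symbol stem were not the whole reason. Without pairs of a symbol family the share was 58.7%, and the highest 2.5% of permuted shares began at 55.7%. Copies such as Hba-a1 and Hba-a2, or with identifier symbols such as LOC, were not recognised as one family, so tandem copies in general stay open. Genes of like abundance lying side by side were not the whole reason either, since permuting within 10 classes of mean abundance put the 2.5% bound at 54.4%. Gain or loss of whole chromosomes stays open as a part of it: the direction differed between chromosomes with a chi-square of 61.0 against 31.1 at the permuted 95% point, with 97 of 152 loci lower on chromosome 13 and 58 of 75 higher on X. Against a lost copy as the reason for each fall, 33 of the 97 loci lower on chromosome 13 had an upper 95% limit below -1, the log2 change of a lost single copy, and the median of the 97, -1.20, was close to that of fallers elsewhere, -1.06, in a table selected for large changes. Whole chromosomes are not enough alone, since permuting within chromosomes put the neighbour bound at 56.3%, and no DNA was measured. Overlapping loci were not left out, so reads shared between overlapping genes under the unstated strand setting also stay open.

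The Cufflinks group values had the opposite sign to DESeq2 for 5 genes of the authors' deposited table: Smpdl3b, Trps1, Aoc3, Nrp1 and LOC361559. Trps1 was at 1.81 and -2.82, Nrp1 at 0.69 and -2.08, and LOC361559 at -1.33 and 4.64 with DESeq2 and Cufflinks in the authors' deposited table. Aoc3 (1.42 and -2.78) shared its Cufflinks locus with G6pc, and Smpdl3b (2.03 and -0.83) with Xkr8. For 15 genes the mean count and the mean CPM of the authors' deposited table were out of proportion by over 1.5 times, and 8 of these had a mean count of at least 5: Rhbg, Htr7, Map2, Bcl2, Slc25a44, Tmem125, Dhtkd1 and Mup5. The ratio was 215 for Mup5, 36.1 for Dhtkd1 and 6.17 for Tmem125, against a median of 14.1. In 22 genes an FPKM of 0 (17 in CSAA, 5 in CDAA) had left spreadsheet error text in place of the Cufflinks fold, and 5 symbols had become dates. By their descriptions the latter were septin 4 (1.34 ± 0.27, SE), membrane associated ring-CH-type finger 3 (1.09 ± 0.24) and finger 6 (-0.77 ± 0.14), and mitochondrial amidoxime reducing component 1 (-2.23 ± 0.15) and component 2 (-1.61 ± 0.14) in the authors' deposited table.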
